A study of Mus musculus with 9 samples.

How the data were processed

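The input was 9 tables of gene counts, 1 per library, as deposited by the authors. Per the submitters' processing notes, adapters were trimmed with cutadapt 1.3, reads were aligned to the mouse genome GRCm38 with STAR 2.4.2a and reads per gene were counted with HTSeq 0.6.1. Per the labels' protocols, stem cells were dissociated, embedded in the matrices and expanded with R-spondin, noggin, EGF, a GSK3 inhibitor and valproic acid. RNA was taken with the RNeasy Micro kit, and libraries were made with a stranded TruSeq mRNA kit. The gene annotation, the strand setting used in counting and the way colonies were taken out of the gels are not given in the sources used here, so genes that overlap others on the opposite strand are uncertain. The sources do not say whether equal replicate numbers share a culture, a day or an animal. The raw reads were not analysed here.

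Each table held 46517 genes followed by 5 tally rows for reads without a gene, which were taken out before analysis. Reads without a feature made up 7.29% to 11.2% of a library's assigned, featureless and ambiguous reads together, and ambiguous reads 1.09% to 1.16%. Reads with more than 1 alignment were left out of that total. Symbols and coordinates came from GENCODE release M21 on GRCm38 and matched 46005 genes, while 512 genes had no match and kept their Ensembl identifier. No count was found in any library for 21125 genes. The edgeR function filterByExpr with the matrix as group kept 14870 genes. No library was left out.

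The comparisons, the gene lists, the rule for named genes and, except where stated, the alternatives were chosen before the data were examined. Libraries were scaled by the trimmed mean of M values (TMM). Each comparison was a contrast in 1 edgeR quasi-likelihood fit of all 9 libraries with 1 mean per matrix, which left 6 residual degrees of freedom beside a median of 5.17 prior degrees of freedom. P-values were adjusted over all tested genes of a comparison by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as changed. The same fit gave the test over all 3 matrices. Standard errors were the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Values in CPM used the TMM-scaled library sizes. Principal components were taken from centred log2 CPM with a prior count of 2. Measures per library were compared by exact permutation tests, for which 3 against 3 libraries allow a p of 0.1 at the lowest. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and, for reading files, the package data.table in version 1.17.8.

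Camera was run on log2 CPM, not on the edgeR fit, with a preset correlation of 0.01 between genes. In total, 35 gene lists were tested, with Benjamini-Hochberg adjustment over the lists of a comparison. They covered stem cells, Wnt targets, YAP/TAZ targets, fetal-like and regenerating epithelium, Paneth, goblet, enteroendocrine and tuft cells and enterocytes. Further lists covered DNA replication, mitosis, integrins, basement membrane and matrix, matrix proteases and inhibitors, actin and SRF targets, NF-kB and inflammation, interferon response, epithelial defence and p53 targets. Others covered hypoxia and glycolysis, cholesterol synthesis, unfolded protein and integrated stress, oxidative stress and xenobiotics, the Notch pathway, BMP targets, immediate early genes and keratins and junctions. The remaining lists marked gastric and squamous epithelium, mesenchymal cells, smooth muscle, glia and neurons, endothelium, blood cells, EHS tumour matrix, mitochondrially encoded genes and replication-dependent histones. Camera with a correlation estimated per list and the rotation test fry were alternatives. With an estimated correlation, camera passed 0 of 35 lists in each comparison. For non-degradable PEG against Matrigel, the tuft list had an estimated correlation of -0.0197, below the preset one. Its camera adjusted p still went from 0.0306 to 0.309. Losing a call under that alternative therefore does not by itself show that the members of a list are correlated. The edgeR test of list members was also adjusted over the list alone.

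Named genes followed a rule. They were the 6 genes with the largest positive and the 6 with the largest negative log2 fold change among changed genes with a mean of at least 5 CPM, no overlap between groups and an assigned symbol. To these were added a panel of 12 marker genes and the 3 members with the smallest p of each list that passed, for at most 6 lists per comparison. The panel gene Dclk1, a tuft cell marker, had too few counts to be tested. Further list members were picked as examples after the results were seen. Some genes that met the rule are not reported.

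The tests were tried on simulated counts in the layout of non-degradable PEG against Matrigel, with 14870 genes of which 100 changed by 2-fold and 100 by 4-fold. The edgeR quasi-likelihood test recovered 74 and 97 of these, with 7 false calls (3.93% of calls). With a replicate block it recovered 72 and 94 (9 false, 5.14%), DESeq2 74 and 93 (33 false, 16.5%), limma-voom 72 and 96 (7 false, 4.00%) and glmTreat 52 and 91 (1 false, 0.694%). The unchanged comparison of degradable PEG against Matrigel gave 0 calls. The test over all 3 matrices recovered 167 of 200 changed genes with 6 false calls. Recovery of changed genes was not measured for the other pairwise comparisons.

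The pairing of libraries by replicate number was checked with the residuals about the matrix means. For non-degradable PEG and Matrigel, same-numbered libraries correlated with r from 0.176 to 0.331 and other pairs from -0.257 to 0.0386 over genes, which are not independent replicates. With the replicate number as a block the comparison gave 3877 changed genes in place of 2504.

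Alternatives were RLE and upper-quartile scaling, no filter, a filter of 10 CPM in 3 libraries, removal of mitochondrial genes and a fit of only the compared groups. Further alternatives were the replicate block, DESeq2, limma-voom, a glmTreat test against a 1.5-fold change, an adjusted p under 0.01 and each library left out in turn. For the principal components they were the 500 most variable genes, RLE scaling and a prior count of 0.5.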

Results

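Polyadenylated RNA was sequenced from colonies of mouse intestinal stem cells grown for 4 days in 1 of 3 matrices, with 3 libraries per matrix and 9 in all. Matrigel is an extract of basement membrane made by a mouse tumour and is rich in laminin and collagen IV. The other matrices were hydrogels of polyethylene glycol (PEG), 1 kind that cells can degrade and 1 kind that they cannot. Each library held between 38.0 M and 47.2 M reads assigned to genes. The means were 44.0 ± 3.97 M reads in Matrigel, 40.7 ± 3.61 M in non-degradable PEG and 38.7 ± 0.6002 M in degradable PEG (SD, n = 3 each). The depth difference between degradable PEG and Matrigel had an exact permutation p of 0.1 (2-sided), the smallest that 3 against 3 allows. Between 19931 and 20648 genes had at least 1 count per library, and 14870 passed the expression filter. At this depth the median standard error of a log2 fold change was 0.112, and the common dispersion corresponded to a biological coefficient of variation of 11.03%. Nothing in the labels says that the 3 libraries of a matrix came from separate cultures or animals, so every p-value measures only the spread between these samples, which may be technical.

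Markers of RNA quality and of cells outside the epithelium were measured beside the gene groups. Mitochondrially encoded genes took 3.35 ± 0.555% of assigned reads in Matrigel, 4.19 ± 0.297% in non-degradable PEG and 3.78 ± 0.607% in degradable PEG (SD, n = 3). The exact permutation p was 0.2 and 0.5 for the PEG gels against Matrigel. Reads with more than 1 alignment numbered 70.9 ± 0.909 per 100 assigned reads in Matrigel, 67.3 ± 1.41 in non-degradable PEG and 66.7 ± 2.36 in degradable PEG. Neither PEG gel overlapped with Matrigel (exact permutation p = 0.1 for each). The 20 most abundant genes took 7.24% to 8.72% of the assigned reads of a library. No library pair was a duplicate, and Pearson correlations across genes, which are not independent replicates, ran from 0.991 to 0.995 within a matrix and from 0.969 to 0.992 between matrices.

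The matrices separated along the principal components of log2 CPM, the counts scaled by library size. PC1 held 52.5% of the variance, with scores from -52.4 to -35.3 in Matrigel and from 11.004 to 35.4 in the PEG gels. PC2 held 14.3%, with scores from 18.0 to 19.0 in non-degradable PEG and from -29.4 to -11.4 in degradable PEG. The mean distance between libraries, as the root mean square log2 difference, was 0.616 between Matrigel and non-degradable PEG, 0.611 between Matrigel and degradable PEG and 0.434 between the PEG gels. It was 0.352, 0.341 and 0.394 within Matrigel, non-degradable PEG and degradable PEG. An edgeR quasi-likelihood test over all 3 matrices, with Benjamini-Hochberg adjustment, found 2424 genes to differ. The count was 1507, 1566 and 1576 without Matrigel replicate 1, 2 or 3.

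**Figure D1:**
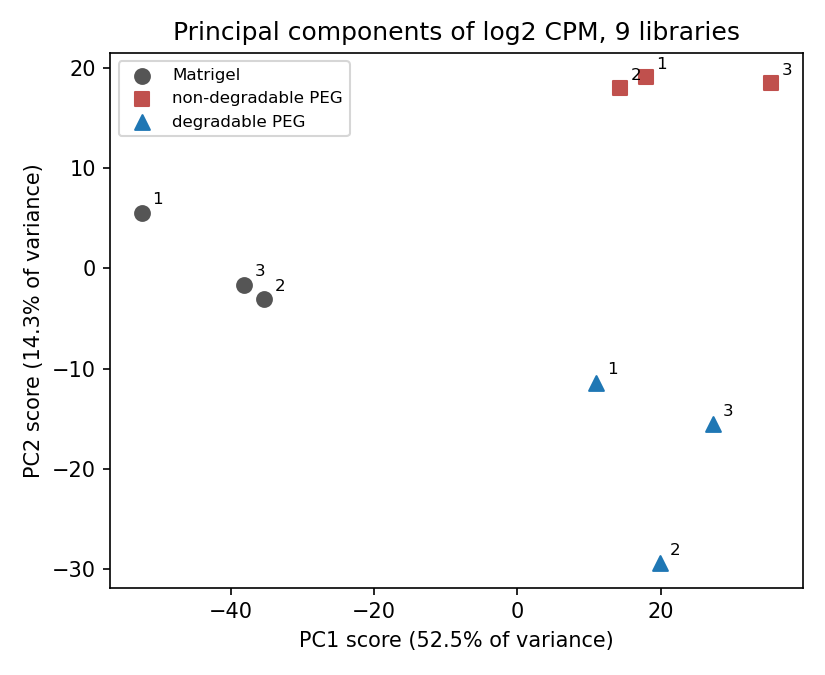
Scores of the 9 libraries on the first principal components of log2 CPM over 14870 genes, in arbitrary units, with the share of variance on each axis and the replicate number beside each point. The Matrigel libraries lie at PC1 scores of -35.3 or lower and the PEG libraries at 11.004 or higher.

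The first comparison set colonies in non-degradable PEG against colonies in Matrigel. Higher in the PEG gel were 23 of 26 immediate early, 23 of 24 hypoxia and 22 of 25 cholesterol synthesis genes, and lower were 11 of 14 Paneth, 9 of 14 enteroendocrine, 4 of 13 goblet and 3 of 6 tuft cell genes. These lists passed camera with the preset correlation and were lost with an estimated one (adjusted p from 0.309 to 0.402). Fos, an AP-1 transcription factor induced within minutes of growth factor stimulation (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, GRCm38), rose from 8.78 ± 4.02 CPM to 1180 ± 857 CPM (SD, n = 3; log2 fold change 7.06 ± 0.596 SE, adjusted p = 6.29e-05). Isx, an intestinal homeobox gene (ENSMUSG00000031621, chromosome 8, 74873173 to 74893506), rose from 1.08 ± 0.873 to 191.0 ± 18.6 CPM (log2 fold change 7.51 ± 0.338, adjusted p = 1.35e-06). Neurog3, the transcription factor that commits cells to the enteroendocrine lineage (ENSMUSG00000044312, chromosome 10, 62133090 to 62134763), fell from 37.8 ± 10.4 to 5.003 ± 1.945 CPM (log2 fold change -2.92 ± 0.304, adjusted p = 1.78e-04). In all, 2504 genes changed, 1444 of them higher and 1060 lower in non-degradable PEG, and 4848 had an unadjusted p under 0.05. At least a 2-fold change was seen for 552 higher and 216 lower genes, and at least an 8-fold change for 58 and 28. The groups did not overlap for 6457 genes, 43.4% where chance gives 10%, and 2491 of the 2504 changed genes were among them. The count was 3877 with the replicate number as a block, 1452 and 1636 without Matrigel replicates 1 and 2, and 1656 and 1189 without non-degradable PEG replicates 1 and 3.

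The immediate early list, genes that respond to growth factors and ERK signalling, had 23 of its 26 measured members higher in non-degradable PEG than in Matrigel and none lower (26 higher when adjusted over the list alone). Its median log2 fold change was 2.43 (camera adjusted p = 1.22e-17, adjusted p = 0.309 with an estimated correlation, lowest of 18 alternatives 6.28e-24). Fosb rose most, by 8.91 ± 0.999 on the log2 scale (adjusted p = 2.58e-04), with 39.5 to 475.9 CPM in the PEG libraries and at most 0.568 CPM in Matrigel. Zfp36, which destabilises cytokine mRNAs, rose by 3.43 ± 0.260 (4.04e-05) and Ier2 by 2.50 ± 0.208 (6.19e-05). The mean log2 CPM over the list was 3.49 in Matrigel and 6.002 in non-degradable PEG, where it ran from 5.36 to 6.80 among the 3 libraries.

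Hypoxia and glycolysis genes, targets of HIF and enzymes of sugar breakdown, rose almost as a block, with 23 of 24 measured members higher and none lower (24 higher when adjusted over the list alone). The median log2 fold change was 1.56 (camera adjusted p = 1.48e-20, adjusted p = 0.309 with an estimated correlation, lowest of 18 alternatives 2.40e-27). Ankrd37, a HIF target, rose by 3.79 ± 0.212 (adjusted p = 3.49e-06), the glycolytic regulator Pfkfb3 by 2.14 ± 0.178 (6.13e-05) and the carbonic anhydrase Car9 by 2.16 ± 0.182 (6.29e-05). Slc16a3, which exports lactate, rose from 4.53 ± 2.44 to 253.6 ± 89.7 CPM (log2 fold change 5.79 ± 0.452, adjusted p = 4.51e-05). The zinc or manganese transporter Slc30a10 rose by 6.19 ± 0.327 (2.89e-06). Cholesterol synthesis genes rose by less but widely, with 22 of 25 members higher and none lower (23 higher when adjusted over the list alone) and a median of 0.53 (camera adjusted p = 6.91e-12, adjusted p = 0.309 with an estimated correlation, lowest of 18 alternatives 1.56e-14). Lanosterol synthase Lss rose by 1.04 ± 0.125 (3.72e-04), the sterol reductase Tm7sf2 by 0.62 ± 0.0818 (6.45e-04) and Insig1 by 1.08 ± 0.143 (6.57e-04).

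Genes of secretory cells fell in non-degradable PEG. Of 14 Paneth cell genes measured, 11 were lower and 1 was higher (12 and 1 when adjusted over the list alone), with a median log2 fold change of -2.95 (camera adjusted p = 1.20e-08, adjusted p = 0.309 with an estimated correlation, lowest of 18 alternatives 4.97e-12). Lysozyme, Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868), fell from 503 ± 197 to 84.1 ± 34.2 CPM (log2 fold change -2.58 ± 0.339, adjusted p = 6.28e-04). The alpha-defensins Defa30, Defa21, Defa22, Defa17 and Defa24 fell, with log2 fold changes of -4.20 ± 0.456 (2.22e-04), -4.03 ± 0.225 (3.49e-06), -3.98 ± 0.271 (1.58e-05), -3.57 ± 0.506 (9.35e-04) and -3.22 ± 0.336 (1.78e-04). Defensins and Lyz1 have near-identical copies in the genome, so the share of each single copy is uncertain. Counts were found for 16 of 39 Defa genes, and their summed CPM was 322 ± 126 in Matrigel and 30.6 ± 12.0 in non-degradable PEG (SD, n = 3). The member that rose, Pla2g2a, encodes a secreted phospholipase (0.62 ± 0.176, adjusted p = 0.0346). Enteroendocrine genes were lower for 9 of 14 members and higher for 2, as when adjusted over the list alone (camera adjusted p = 2.02e-04, adjusted p = 0.309 with an estimated correlation, lowest of 18 alternatives 5.74e-06). Chromogranin A, Chga, fell by 1.72 ± 0.264 (0.00159), while the neuropeptide gene Nts rose by 1.03 ± 0.217 (0.00875). Counts of Chga were low, at 2.42 to 4.20 CPM in Matrigel and 0.661 to 1.22 CPM in non-degradable PEG. Goblet cell genes were lower for 4 of 13 members and higher for none, also when adjusted over the list alone (camera adjusted p = 0.00212, adjusted p = 0.402 with an estimated correlation, lowest of 17 alternatives 4.66e-05; 0.0552 with fry). Trefoil factor Tff3 fell by 1.82 ± 0.181 (1.60e-04), and the mucin Muc2 changed by -0.58 ± 0.413 and did not pass (0.361). Tuft cell genes were lower for 3 of 6 members and higher for none, also when adjusted over the list alone (camera adjusted p = 0.0306, adjusted p = 0.309 with an estimated correlation, lowest of 17 alternatives 0.00265). Trpm5, the taste-pathway channel of tuft cells, fell by 3.24 ± 0.342 (1.84e-04). The tuft list missed the threshold with no filter (0.134), with the replicate block (0.101) and without Matrigel replicate 3 (0.0526) or non-degradable PEG replicate 1 (0.0554).

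Stem cell and absorptive genes moved in both directions. Lgr5, the R-spondin receptor that marks crypt base stem cells (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780), stood at 195.3 ± 28.0 CPM in Matrigel and 198.3 ± 15.9 CPM in non-degradable PEG (log2 fold change 0.02 ± 0.131, adjusted p = 0.927). Its sign turned to -0.05 and -0.02 without Matrigel replicates 2 and 3 and to -0.04 without non-degradable PEG replicate 1. Ascl2, a transcription factor of the same cells, rose by 0.76 ± 0.111 (0.00117), and Olfm4, a secreted stem cell marker, fell by 1.23 ± 0.279 (0.0129). The stem cell list had 2 members higher and 3 lower of 19 (2 and 5 when adjusted over the list alone) and did not pass (camera adjusted p = 0.141). Among 17 Wnt targets, 4 rose and 4 fell (4 and 5 when adjusted over the list alone; camera adjusted p = 0.901). The list's median of 0.03 differed in sign from its mean of -0.08. Axin2, a negative regulator of Wnt signalling, fell by 0.30 ± 0.0880 (adjusted p = 0.0394). Its adjusted p rose to between 0.0593 and 0.122 without any 1 of the 3 Matrigel or 3 non-degradable PEG libraries, and ran from 0.00767 to 1.00 over 19 alternatives. Enterocyte genes had 5 members higher and 3 lower of 20 (10 and 3 when adjusted over the list alone), with the list higher as a whole (median 0.44, camera adjusted p = 0.0443, adjusted p = 0.531 with an estimated correlation, lowest of 18 alternatives 0.00186). The alkaline phosphatase Alpi rose by 1.37 ± 0.352 (0.0230) although the groups overlapped, and the aminopeptidase Anpep fell by 0.89 ± 0.183 (0.00775). The enterocyte call was lost without Matrigel replicates 2 (0.2) and 3 (0.149), non-degradable PEG replicates 1 (0.0765) and 3 (0.146) and degradable PEG replicates 1 (0.0522), 2 (0.0566) and 3 (0.0656). It was also lost for enterocyte genes with fry (0.170), upper-quartile scaling, a filter of 10 CPM (0.202) and a fit of the compared groups only (0.0551), so that 12 of 18 alternatives ended it. Alpi missed the threshold without Matrigel replicates 2 (0.0823) and 3 (0.0768) and non-degradable PEG replicates 1 (0.0606) and 3 (0.100), within a range from 2.38e-04 to 0.184 over 18 alternatives.

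Cell cycle genes were lower by small amounts in non-degradable PEG. Mitosis genes fell for 17 of 24 members (24 when adjusted over the list alone), with a median log2 fold change of -0.38 (camera adjusted p = 3.39e-10, adjusted p = 0.345 with an estimated correlation, lowest of 18 alternatives 1.25e-12). The spindle genes Nusap1, Tpx2 and Bub1b fell, with -0.41 ± 0.0729 (0.00357), -0.38 ± 0.0735 (0.00560) and -0.35 ± 0.0688 (0.00642). The proliferation marker Mki67 changed by -0.35 ± 0.136 and did not pass (0.0983). It passed with the replicate block (0.0257) and without non-degradable PEG replicate 2 (0.0490), with a range from 0.0184 to 1.00 over 19 alternatives. DNA replication genes fell for 15 of 25 members (19 when adjusted over the list alone), with a median of -0.31 (camera adjusted p = 3.50e-08, adjusted p = 0.359 with an estimated correlation, lowest of 18 alternatives 4.35e-10). The DNA primase subunit Prim1, the chromatin assembly factor Chaf1a and thymidylate synthase Tyms fell, with -0.51 ± 0.0771 (0.00150), -0.39 ± 0.0809 (0.00790) and -0.51 ± 0.114 (0.0123). Neither list had a member that rose. Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, were higher for 5 of 12 members and lower for none (6 higher when adjusted over the list alone; camera adjusted p = 3.69e-04, adjusted p = 0.309 with an estimated correlation, lowest of 17 alternatives 1.21e-04), with Hist1h1d higher by 3.13 ± 0.362 (2.96e-04).

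Lists of regenerating epithelium, inflammation and YAP/TAZ targets passed as higher in non-degradable PEG. The list of fetal-like and regenerating epithelium had 10 of 15 members higher and none lower (11 higher when adjusted over the list alone), with a median of 1.35 (camera adjusted p = 4.02e-08, adjusted p = 0.309 with an estimated correlation, lowest of 18 alternatives 3.55e-13). Mesothelin, Msln, rose by 3.95 ± 0.258 (1.26e-05), and Ly6a, the Sca-1 antigen of fetal spheroids, by 1.83 ± 0.296 (0.00214). Sprr2a3, a small proline-rich protein with close copies, rose by 5.96 ± 0.276 (1.35e-06). Of 20 NF-kB and inflammation genes, 10 rose and 1 fell (12 and 1 when adjusted over the list alone; camera adjusted p = 2.20e-06, adjusted p = 0.345 with an estimated correlation, lowest of 18 alternatives 2.25e-07). The neutrophil chemokine Cxcl1 rose by 2.37 ± 0.486 (0.00765). YAP/TAZ targets rose for 3 of 19 members (5 when adjusted over the list alone), and none fell (camera adjusted p = 0.0270, adjusted p = 0.402 with an estimated correlation, lowest of 18 alternatives 0.00352). Those 3 were Ccn2 (3.23 ± 0.305, adjusted p = 1.24e-04), Ccn1 (3.45 ± 0.254, 3.12e-05) and Ankrd1 (4.22 ± 0.332, 4.51e-05). The YAP/TAZ list missed the threshold with a filter of 10 CPM (0.0670), with the replicate block (0.0528) and without Matrigel replicate 3 (0.0586).

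Matrix proteases and their inhibitors had 6 of 16 members higher and none lower (7 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.0355, adjusted p = 0.402 with an estimated correlation, lowest of 18 alternatives 0.00638). That list was lost in a fit of the compared groups only, with the replicate block (0.0617) and without Matrigel replicates 1 (0.0694) and 3 (0.0595), non-degradable PEG replicates 2 (0.0553) and 3 (0.0780) and degradable PEG replicates 1 (0.0567) and 3 (0.0780). BMP targets rose for 4 of 13 members and fell for 1 (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0170, adjusted p = 0.359 with an estimated correlation, lowest of 18 alternatives 7.77e-04), with Id1 higher by 2.80 ± 0.314 (2.58e-04). Interferon response genes rose for 4 of 16 and fell for 1 (6 and 2 when adjusted over the list alone; camera adjusted p = 0.00288, adjusted p = 0.345 with an estimated correlation, lowest of 18 alternatives 4.89e-04; 0.263 with a filter of 10 CPM). Targets of p53 rose for 6 of 20 and fell for none (9 higher when adjusted over the list alone; camera adjusted p = 0.00370, adjusted p = 0.402 with an estimated correlation, lowest of 18 alternatives 4.67e-05). Unfolded protein and integrated stress genes rose for 7 of 20 and fell for none (11 and 1 when adjusted over the list alone; camera adjusted p = 0.00803, adjusted p = 0.377 with an estimated correlation, lowest of 18 alternatives 0.00133). Epithelial defence genes rose for 3 of 10 and fell for none, also when adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.359 with an estimated correlation, lowest of 18 alternatives 1.29e-04; 0.0743 without Matrigel replicate 3 and 0.0630 with a filter of 10 CPM). Oxidative stress and xenobiotic genes rose for 5 of 21 and fell for 1 (6 and 1 when adjusted over the list alone; camera adjusted p = 0.0352, adjusted p = 0.402 with an estimated correlation, lowest of 18 alternatives 0.00875). Their call was lost with the replicate block (0.0581) and without Matrigel replicate 3 (0.228) or non-degradable PEG replicate 2 (0.0833).

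Lists that did not pass in non-degradable PEG against Matrigel included those for other cell types and for traces of the matrix itself. Basement membrane and matrix genes had 6 members higher and 2 lower of 18 (9 and 3 when adjusted over the list alone; camera adjusted p = 0.0531), with the collagen IV chain gene Col4a1 higher by 2.30 ± 0.364 (0.00184). The list passed without Matrigel replicates 2 (0.0126) and 3 (0.0375) or non-degradable PEG replicate 1 (0.0454), within 0.0107 to 0.402 over 18 alternatives. The list of EHS tumour matrix genes, which RNA left in Matrigel would bring, had 4 members higher and 1 lower of 10, also when adjusted over the list alone (0.0577), so that its direction was higher in the PEG gel. It passed without Matrigel replicates 1 (0.0293) and 2 (0.0252), non-degradable PEG replicate 2 (0.0434) and degradable PEG replicate 3 (0.0493), within 0.00797 to 0.309 over 18 alternatives. Integrins had 1 member higher and 1 lower of 15 (0.308), and actin and SRF targets 4 and 2 of 18 (0.163). The Notch pathway had 3 and 4 of 15 (0.786), and keratins and junctions 5 and 1 of 25 (0.0579; 0.0167 without non-degradable PEG replicate 2, range 0.0113 to 0.454). Markers of mesenchymal cells had 1 of 5 members lower (0.850), of smooth muscle, glia and neurons 1 of 6 lower (0.123), of endothelium 1 of 5 higher (0.256), of blood cells 1 of 3 higher (0.0591) and of gastric and squamous epithelium 1 of 4 higher (0.326). Median and mean differed in sign for mesenchymal cells (0.13 and -0.15) and gastric and squamous epithelium (-0.03 and 1.10). Mitochondrially encoded genes had 1 of 7 members higher (0.0971; 0.0230 without Matrigel replicate 3, range 0.0199 to 0.454). The blood cell and mitochondrial lists passed with the replicate block (0.0355 and 0.0199), and the blood cell list also without Matrigel replicate 1 (0.0438, range 0.00797 to 0.926). Of the 35 lists, 15 passed as higher and 6 as lower with the preset correlation, 19 with the block and 0 with an estimated correlation (3 at an unadjusted p under 0.05). Fry passed 25, and another split of the same 6 libraries passed 21. A glmTreat test against a 1.5-fold change left 478 genes and ended the calls of Ascl2, Olfm4, Axin2, Alpi, Tm7sf2 and the named cell cycle genes.

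**Figure D2:**
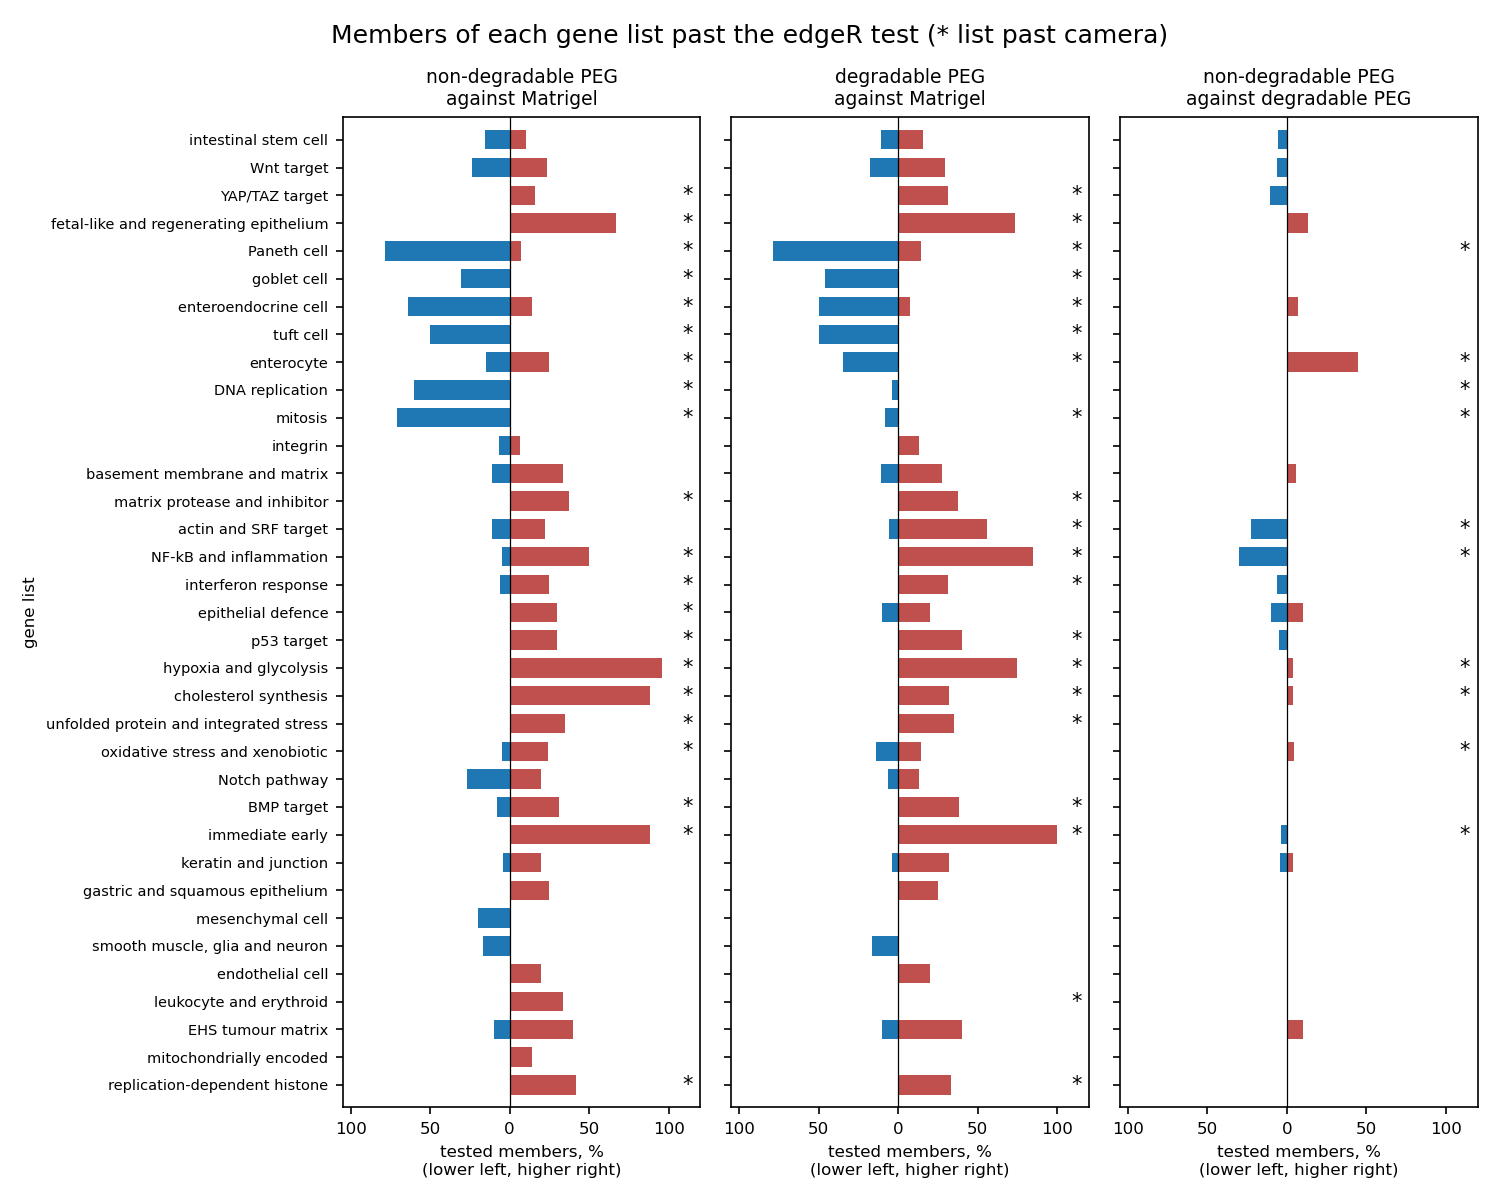
Share of the measured members of each of 35 gene lists that passed the edgeR quasi-likelihood test, in percent, lower to the left and higher to the right, for the 3 comparisons; asterisks mark lists past the camera test with the preset correlation. Of 26 immediate early genes, 23 were higher in non-degradable PEG and 26 in degradable PEG than in Matrigel.

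The second comparison set colonies in degradable PEG against colonies in Matrigel. Higher in the degradable gel were 26 of 26 immediate early, 17 of 20 inflammation and 18 of 24 hypoxia genes, and lower were 11 of 14 Paneth, 7 of 14 enteroendocrine, 6 of 13 goblet, 3 of 6 tuft cell and 7 of 20 enterocyte genes. These lists passed camera with the preset correlation and were lost with an estimated one (adjusted p from 0.232 to 0.333). Fos rose to 1274 ± 323 CPM from 8.78 ± 4.02 CPM (SD, n = 3; log2 fold change 7.17 ± 0.599, adjusted p = 6.88e-05). The stress-induced transcription factor Atf3 rose from 5.25 ± 1.31 to 468.9 ± 114.7 CPM (log2 fold change 6.48 ± 0.914, adjusted p = 0.00114). Tnf, a cytokine that activates NF-kB (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), rose from 1.5015 ± 0.439 to 35.1 ± 9.62 CPM (log2 fold change 4.53 ± 0.347, adjusted p = 4.06e-05). In all, 1815 genes changed, 1103 higher and 712 lower, with 4057 at an unadjusted p under 0.05. At least a 2-fold change was seen for 496 higher and 213 lower genes, and at least an 8-fold change for 60 and 19. The groups did not overlap for 4519 genes, 30.4% where chance gives 10%, and 1813 of the 1815 changed genes were among them. The count was 1086 and 1177 without Matrigel replicates 1 and 3 and 1178 without degradable PEG replicate 3.

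All 26 immediate early genes measured were higher in degradable PEG than in Matrigel (26 when adjusted over the list alone), with a median of 2.96 (camera adjusted p = 2.34e-27, adjusted p = 0.232 with an estimated correlation, lowest of 18 alternatives 3.0e-35). Beside Fos and Atf3, Fosb rose by 9.60 ± 1.01 (2.22e-04), Egr2 by 6.004 ± 0.589 (1.61e-04), Zfp36 by 3.58 ± 0.262 (4.06e-05) and Ier2 by 2.81 ± 0.211 (4.06e-05). Arc, an activity-induced gene outside the lists, rose by 5.74 ± 0.606 (2.22e-04), and Isx by 6.83 ± 0.333 (4.76e-06). NF-kB and inflammation genes rose for 17 of 20 members and fell for none (18 and 1 when adjusted over the list alone), with a median of 1.34 (camera adjusted p = 1.44e-15, adjusted p = 0.232 with an estimated correlation, lowest of 18 alternatives 3.76e-19). Inducible nitric oxide synthase Nos2 rose by 4.02 ± 0.327 (6.06e-05), the cytokine Lif by 2.14 ± 0.163 (4.06e-05) and Cxcl1 by 4.28 ± 0.490 (3.36e-04). Actin and SRF targets rose for 10 of 18 members and fell for 1 (12 and 1 when adjusted over the list alone; camera adjusted p = 1.51e-05, adjusted p = 0.232 with an estimated correlation, lowest of 18 alternatives 2.76e-07). The focal adhesion protein Zyx rose by 0.97 ± 0.108 (2.73e-04), the transcription factor Srf by 1.04 ± 0.117 (2.98e-04) and Actg1, an actin with near-identical copies and therefore uncertain, by 1.21 ± 0.114 (1.39e-04). YAP/TAZ targets rose for 6 of 19 members and fell for none, also when adjusted over the list alone (camera adjusted p = 0.00312, adjusted p = 0.333 with an estimated correlation, lowest of 18 alternatives 2.79e-04), with Ccn2 higher by 3.06 ± 0.304 (1.70e-04).

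Hypoxia and glycolysis genes rose for 18 of 24 members in degradable PEG and fell for none (22 higher when adjusted over the list alone), with a median of 1.13 (camera adjusted p = 1.46e-15, adjusted p = 0.232 with an estimated correlation, lowest of 18 alternatives 3.76e-19). Ankrd37 rose by 3.20 ± 0.210 (1.71e-05), the vasodilator peptide gene Adm by 3.00 ± 0.269 (1.09e-04) and Pfkfb3 by 1.84 ± 0.177 (1.42e-04). Fetal-like and regenerating epithelium genes rose for 11 of 15 members and fell for none (12 higher when adjusted over the list alone), with a median of 1.38 (camera adjusted p = 7.11e-10, adjusted p = 0.232 with an estimated correlation, lowest of 18 alternatives 2.34e-15). The EGF receptor ligands Ereg and Areg rose by 2.11 ± 0.226 (2.36e-04) and 2.00 ± 0.229 (3.36e-04), and Msln by 2.30 ± 0.255 (2.68e-04). Cholesterol synthesis genes rose for 8 of 25 members and fell for none (12 higher when adjusted over the list alone; camera adjusted p = 2.41e-05, adjusted p = 0.372 with an estimated correlation, lowest of 18 alternatives 2.76e-07; 0.0509 with fry). Mitosis genes fell for 2 of 24 members and rose for none (1 lower when adjusted over the list alone; median -0.20, camera adjusted p = 3.78e-05, adjusted p = 0.401 with an estimated correlation, lowest of 18 alternatives 2.29e-06; 0.0798 with fry). Mki67 changed by -0.27 ± 0.136 (0.220). DNA replication genes had 1 of 25 members lower, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.155; 0.0321 without Matrigel replicate 3, range 0.0321 to 0.708 over 18 alternatives).

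Paneth cell genes fell for 11 of 14 members in degradable PEG and rose for 2 (12 and 2 when adjusted over the list alone), with a median of -3.03 (camera adjusted p = 1.33e-07, adjusted p = 0.232 with an estimated correlation, lowest of 18 alternatives 3.10e-10). Lyz1 fell by 2.97 ± 0.345 (3.59e-04), and Defa30, Defa17, Defa21, Defa24 and Defa22, uncertain as single copies, had log2 fold changes of -4.13 ± 0.454 (2.53e-04), -3.48 ± 0.503 (0.00130), -3.26 ± 0.212 (1.71e-05), -3.24 ± 0.337 (2.22e-04) and -3.08 ± 0.253 (6.37e-05). The summed defensin CPM was 31.8 ± 10.6 in degradable PEG (SD, n = 3). Pla2g2a (1.37 ± 0.178, adjusted p = 6.68e-04) and the defensin-processing protease Mmp7 (0.79 ± 0.209, 0.0312) rose. Goblet cell genes fell for 6 of 13 members and rose for none (7 lower when adjusted over the list alone; camera adjusted p = 1.53e-04, adjusted p = 0.333 with an estimated correlation, lowest of 17 alternatives 1.12e-06). Muc2 fell by 1.82 ± 0.445 (0.0221), a call lost without Matrigel replicate 1 (0.0790) or degradable PEG replicates 2 (0.0730) and 3 (0.0832), with a range from 1.60e-04 to 0.118 over 18 alternatives. Counts of Muc2 were low, at 2.18 to 6.17 CPM in Matrigel and 0.724 to 1.39 CPM in degradable PEG. Enteroendocrine genes fell for 7 of 14 members and rose for 1 (9 and 1 when adjusted over the list alone; camera adjusted p = 1.36e-04, adjusted p = 0.232 with an estimated correlation, lowest of 18 alternatives 3.35e-06). Chga fell by 1.04 ± 0.254 (0.0215), a call lost without Matrigel replicates 1 (0.0812) and 3 (0.0573) or degradable PEG replicates 2 (0.0619) and 3 (0.0760), with a range from 0.00221 to 0.290. It stood at 1.47 to 1.71 CPM in degradable PEG. Tuft cell genes fell for 3 of 6 members and rose for none, also when adjusted over the list alone (camera adjusted p = 0.0344, adjusted p = 0.232 with an estimated correlation, lowest of 17 alternatives 0.00434; 0.154 without degradable PEG replicate 1 and 0.135 with no filter). Enterocyte genes fell for 7 of 20 members and rose for none (10 lower when adjusted over the list alone), with a median of -0.75 (camera adjusted p = 3.78e-05, adjusted p = 0.333 with an estimated correlation, lowest of 18 alternatives 1.82e-06). The disaccharidase Sis fell by 2.31 ± 0.371 (0.00230), and Alpi changed by -0.87 ± 0.372 (0.156).

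Stem cell genes in degradable PEG had 3 members higher and 2 lower of 19, also when adjusted over the list alone (camera adjusted p = 0.746). Ascl2 rose by 0.92 ± 0.111 (4.85e-04). Lgr5 stood at 155.0 ± 27.2 CPM (log2 fold change -0.33 ± 0.131, adjusted p = 0.127). It passed with the replicate block (0.00949) and without degradable PEG replicate 1 (-0.47, adjusted p = 0.0310, range 0.00949 to 1.00 over 19 alternatives). Olfm4 changed by -0.78 ± 0.275 (0.0916). It passed with the replicate block (0.00127) and without Matrigel replicate 2 (0.0338) or non-degradable PEG replicate 2 (0.0490), with a range from 0.00127 to 1.00. Axin2 changed by 0.21 ± 0.0879 (0.153) and passed without degradable PEG replicate 2 (0.0296, range 0.0296 to 1.00). Wnt targets had 5 members higher and 3 lower of 17 (6 and 5 when adjusted over the list alone; camera adjusted p = 0.316).

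Among the other lists, matrix proteases and inhibitors rose for 6 of 16 members in degradable PEG and fell for none (7 higher when adjusted over the list alone; camera adjusted p = 0.0056, adjusted p = 0.340 with an estimated correlation, lowest of 18 alternatives 0.00195). BMP targets rose for 5 of 13 and fell for none (8 higher when adjusted over the list alone; camera adjusted p = 0.0056, adjusted p = 0.333 with an estimated correlation, lowest of 18 alternatives 0.00168). Interferon response genes rose for 5 of 16 and fell for none (8 and 1 when adjusted over the list alone; camera adjusted p = 1.82e-04, adjusted p = 0.232 with an estimated correlation, lowest of 18 alternatives 3.98e-06; 0.115 with a filter of 10 CPM). Targets of p53 rose for 8 of 20 and fell for none, also when adjusted over the list alone (camera adjusted p = 2.43e-04, adjusted p = 0.347 with an estimated correlation, lowest of 18 alternatives 3.28e-06). Unfolded protein and integrated stress genes rose for 7 of 20 and fell for none (10 and 1 when adjusted over the list alone; camera adjusted p = 0.00503, adjusted p = 0.333 with an estimated correlation, lowest of 18 alternatives 8.85e-04). Replication-dependent histones rose for 4 of 12 and fell for none (6 higher when adjusted over the list alone; camera adjusted p = 1.94e-04, adjusted p = 0.232 with an estimated correlation, lowest of 17 alternatives 4.32e-05). The blood cell list passed with 0 of its 3 members past the edgeR test (3 higher when adjusted over the list alone; camera adjusted p = 0.0465, adjusted p = 0.232 with an estimated correlation). That call was lost with upper-quartile scaling (0.0615), with no filter (0.520) and without any 1 library other than Matrigel replicate 1, with an adjusted p from 0.0826 to 0.729 and a range from 0.0101 to 0.729 over 17 alternatives. No call was made for epithelial defence (2 higher, 1 lower of 10; camera adjusted p = 0.0593; 0.00200 without Matrigel replicate 1, range 0.00200 to 0.390) or oxidative stress (3 and 3 of 21; 0.155; 0.0101 without Matrigel replicate 3, range 0.0101 to 0.557). The same held for keratins and junctions (8 and 1 of 25; 0.0651; 0.0472 without Matrigel replicate 1 and 0.0283 without degradable PEG replicate 2, range 0.0261 to 0.510). Integrins (2 higher of 15; 0.275), basement membrane (5 and 2 of 18; 0.263), EHS tumour matrix (4 and 1 of 10; 0.224), the Notch pathway (2 and 1 of 15; 0.508) and mitochondrially encoded genes (0 of 7; 0.445) did not pass either. Nor did gastric and squamous epithelium (1 higher of 4; 0.172), mesenchymal cells (0 of 5; 0.508), smooth muscle, glia and neurons (1 lower of 6; 0.172) and endothelium (1 higher of 5; 0.0879). Of the 35 lists, 14 passed as higher and 6 as lower with the preset correlation, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 23 with fry. Another split of the same 6 libraries passed 18. A glmTreat test against a 1.5-fold change left 437 genes and ended the calls of Muc2 and Chga.

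**Figure D3:**
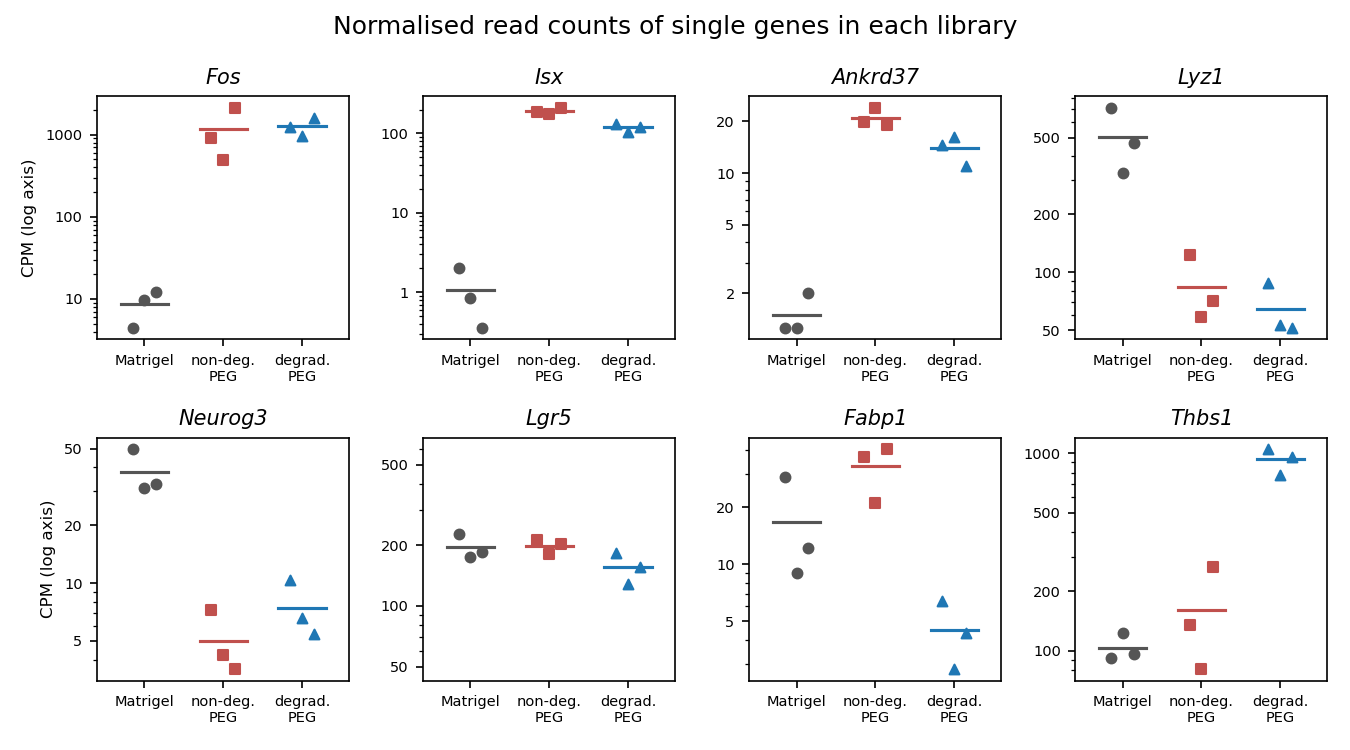
Normalised read counts in CPM (log axis) of 8 genes in each library, with 3 points per matrix in the order of the replicate number and a line at the group mean. Fos lies between 4.40 and 12.3 CPM in Matrigel and at 488.3 CPM or more in both PEG gels, and Thbs1 at 779.2 CPM or more in degradable PEG and at 266.9 CPM or less elsewhere.

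Many changes against Matrigel were shared by the PEG gels. Of the genes called in both comparisons, 764 were higher and 421 lower in both, 1185 in all, and 2 went in opposite directions. Lists drawn independently would share 107 higher and 50.8 lower genes. In 20 simulations without any change, where both comparisons used the same simulated Matrigel libraries, 0 calls were shared in the edgeR test. Unchanged groups give few calls of any kind, so that 0 does not show what overlap shared controls bring to changed groups. Called against Matrigel only in non-degradable PEG were 1317 genes and only in degradable PEG 628, which does not show that they differed between the gels. The fold changes correlated with r = 0.84 across 14870 genes, which are not independent replicates, where the simulated value was 0.488. Their covariance was 0.284 against a simulated 0.0227, a difference of 0.261, and 77.2% of genes had the same sign, against 66.4% simulated. The 3 Matrigel libraries cannot be split into parts of at least 2, so part of the excess in overlap may come from the shared controls. The overlap was 697 and 765 genes without Matrigel replicates 1 and 3.

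The third comparison tested the gels directly and asked what the ability to degrade the PEG gel goes with. The enterocyte list was higher in non-degradable PEG, with 9 of 20 members past the test, and the inflammation and actin lists were lower, with 6 of 20 and 4 of 18. These camera calls rest on the preset correlation and were lost with an estimated one (adjusted p = 0.408 for each). Fabp1, the fatty acid binding protein of liver and gut (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023), stood at 32.7 ± 10.3 CPM in non-degradable and 4.54 ± 1.83 CPM in degradable PEG, with 16.6 ± 10.5 CPM in Matrigel (SD, n = 3; log2 fold change 2.85 ± 0.440, adjusted p = 0.0152). Thbs1, the matricellular glycoprotein thrombospondin 1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), stood at 160.6 ± 96.0 CPM in non-degradable and 931 ± 140.0 CPM in degradable PEG (log2 fold change -2.54 ± 0.341, adjusted p = 0.0111). Far fewer genes passed than against Matrigel, 190 in all, with 121 higher and 69 lower in non-degradable PEG, 62 and 25 of them by at least 2-fold. There were 2203 at an unadjusted p under 0.05. The groups did not overlap for 2832 genes, 19.0% where chance gives 10%, and all 190 were among them. Of the 121 higher genes, 43 had both gel means above Matrigel, 18 both below and 60 on opposite sides. Of the 69 lower genes the numbers were 34, 4 and 31. The count was 521 without a filter on low counts and 511 with DESeq2. It fell to 28 and 124 without non-degradable PEG replicates 1 and 2 and to 117 and 19 without degradable PEG replicates 1 and 2. Without non-degradable PEG replicate 3 the split turned to 51 higher and 92 lower, and without degradable PEG replicate 2 to 4 and 15.

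Enterocyte genes were higher in non-degradable PEG for 9 of 20 members and lower for none (19 higher when adjusted over the list alone), with a median log2 fold change of 0.90 (camera adjusted p = 2.75e-15, adjusted p = 0.408 with an estimated correlation, lowest of 18 alternatives 2.05e-18). Beside Fabp1, the disaccharidase Sis was higher by 2.41 ± 0.372 (0.0152), Alpi by 2.24 ± 0.370 (0.0202) and the apolipoprotein Apoa1 by 2.71 ± 0.405 (0.0147). Counts of Apoa1 were low, at 1.35 to 2.27 CPM in non-degradable and 0.233 to 0.368 CPM in degradable PEG. Those of Alpi were 6.43 to 17.3 and 2.33 to 2.92 CPM. Outside the list, the alcohol dehydrogenase Adh6a was higher by 2.47 ± 0.364 (0.0145) and the monooxygenase Fmo5 by 1.98 ± 0.263 (0.0111). Fabp1, Sis and Apoa1 missed the threshold without non-degradable PEG replicate 1 (0.0609, 0.0594 and 0.0594) or degradable PEG replicate 2 (0.0966, 0.0827 and 0.0883). So did Alpi without non-degradable PEG replicate 1 (0.0829) or degradable PEG replicates 2 (0.117) and 3 (0.0516). Adh6a and Fmo5 missed it without degradable PEG replicate 2 (0.0783 and 0.0596). Over 18 or 19 alternatives the adjusted p of these 6 genes ran up to between 0.123 and 0.141.

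The inflammation, actin and immediate early lists passed camera as lower in non-degradable than in degradable PEG. NF-kB and inflammation genes were lower for 6 of 20 members and higher for none (14 and 1 when adjusted over the list alone), with a median of -0.76 (camera adjusted p = 1.78e-10, adjusted p = 0.408 with an estimated correlation, lowest of 18 alternatives 6.01e-15). Tnf had a log2 fold change of -1.89 ± 0.292 (0.0152), the NF-kB inhibitor Tnfaip3 had -1.31 ± 0.183 (0.0128), the chemokine Cxcl5 -1.34 ± 0.204 (0.0152) and Cxcl1 -1.91 ± 0.420, which did not pass (0.0578). Actin and SRF targets were lower for 4 of 18 members and higher for none (8 lower when adjusted over the list alone; median -0.20, camera adjusted p = 4.60e-06, adjusted p = 0.408 with an estimated correlation, lowest of 18 alternatives 2.77e-09), with Zyx at -0.94 ± 0.108 (0.00994). Acta1, the skeletal muscle actin and an SRF target, had -1.85 ± 0.228 (0.0103), the NADPH oxidase Nox1 -1.83 ± 0.286 (0.0159), Wnt6 -1.57 ± 0.243 (0.0152) and the peptide endothelin, Edn1, -1.57 ± 0.253 (0.0188). Immediate early genes were lower for 1 of 26 members (7 when adjusted over the list alone; median -0.43, camera adjusted p = 8.67e-10, adjusted p = 0.601 with an estimated correlation, lowest of 18 alternatives 6.51e-27). The member was Fosl2 (-0.72 ± 0.111, adjusted p = 0.0152), while Klf6 (-1.41 ± 0.320, 0.0649) and Ier3 (-1.07 ± 0.253, 0.0770) did not pass. Tnf, Cxcl5, Wnt6 and Edn1 missed the threshold without non-degradable PEG replicate 1 (0.0837, 0.0829, 0.0758 and 0.0837) or degradable PEG replicate 2 (0.0658, 0.0810, 0.0827 and 0.0783). Thbs1, Tnfaip3 and Fosl2 missed it without non-degradable PEG replicate 1 (0.0534, 0.0589 and 0.0812). Cxcl1 passed without non-degradable PEG replicate 3 (0.00695) or degradable PEG replicate 1 (0.0383). Klf6 passed without non-degradable PEG replicate 3 (0.00192) and Ier3 without Matrigel replicates 1 (0.0144) and 2 (0.0393). Over 18 or 19 alternatives the highest adjusted p of these genes lay between 0.123 and 1.00.

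The hypoxia, cholesterol and oxidative stress lists passed camera as higher in non-degradable than in degradable PEG, with 1 member each past the edgeR test. Hypoxia and glycolysis genes were higher for 1 of 24 members (16 when adjusted over the list alone; median 0.39, camera adjusted p = 9.70e-10, adjusted p = 0.408 with an estimated correlation, lowest of 18 alternatives 3.37e-12). The member was Gapdh (0.89 ± 0.154, adjusted p = 0.0229), which shares reads with many pseudogenes and is uncertain, while Kdm3a (0.35 ± 0.0782, 0.0615) and Ndrg1 (1.12 ± 0.252, 0.0636) did not pass. Cholesterol synthesis genes were higher for 1 of 25 members, Lss (0.60 ± 0.124, adjusted p = 0.0439), and for 13 when adjusted over the list alone (median 0.27, camera adjusted p = 9.70e-10, adjusted p = 0.601 with an estimated correlation, lowest of 18 alternatives 1.79e-13). Cyp51 (0.36 ± 0.0960, 0.119) and Sc5d (0.35 ± 0.0964, 0.122) did not pass. Oxidative stress and xenobiotic genes were higher for 1 of 21 members (10 when adjusted over the list alone; median 0.35, camera adjusted p = 9.87e-07, adjusted p = 0.408 with an estimated correlation, lowest of 18 alternatives 2.94e-08). Gapdh missed the threshold without non-degradable PEG replicates 1 (0.104) and 2 (0.0590) or degradable PEG replicates 2 (0.0982) and 3 (0.0595), with a highest value of 0.895 over 19 alternatives. Lss missed it without each Matrigel library (0.0517, 0.0619 and 0.0726), non-degradable PEG replicates 1 (0.137) and 3 (0.0957) and degradable PEG replicates 1 (0.0903) and 2 (0.176), with a highest value of 1.00. Ndrg1 passed without Matrigel replicate 1 (0.0458), non-degradable PEG replicate 2 (0.0304) or degradable PEG replicate 3 (0.0386), within 5.57e-05 to 0.836.

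Cell cycle and Paneth cell lists were lower in non-degradable than in degradable PEG with 0 members past the edgeR test over all genes. DNA replication genes had 14 of 25 members lower when adjusted over the list alone (median -0.22, camera adjusted p = 2.98e-10, adjusted p = 0.601 with an estimated correlation, lowest of 18 alternatives 1.30e-11). Mcm3, Cdc45 and Cdc6 had -0.26 ± 0.0718 (0.127), -0.33 ± 0.0902 (0.127) and -0.21 ± 0.0619 (0.146). Mitosis genes had 0 of 24 members lower either way (median -0.15, camera adjusted p = 8.15e-06, adjusted p = 0.753 with an estimated correlation, lowest of 18 alternatives 2.51e-08). Mki67 had -0.08 ± 0.136 (0.822), with the sign turned without non-degradable PEG replicate 3 (0.05) or degradable PEG replicate 1 (0.03). Paneth cell genes had 3 of 14 members lower when adjusted over the list alone (median -0.25, camera adjusted p = 0.0169, adjusted p = 0.753 with an estimated correlation, lowest of 18 alternatives 0.00196; 0.157 without non-degradable PEG replicate 2, 0.197 without degradable PEG replicate 1 and 0.0696 with a filter of 10 CPM). Lyz1 had 0.39 ± 0.324 (0.602).

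Among the panel genes not yet given for this comparison, Axin2 was lower in non-degradable PEG (461.3 ± 33.8 against 655.7 ± 71.6 CPM; log2 fold change -0.51 ± 0.0881, adjusted p = 0.0241). That call was lost without non-degradable PEG replicates 1 (0.0909) and 2 (0.0729) or degradable PEG replicates 1 (0.0504) and 3 (0.0595), with a range from 4.18e-05 to 1.00 over 19 alternatives. Lgr5 (0.36 ± 0.132, 0.252), Ascl2 (-0.16 ± 0.110, 0.525), Olfm4 (-0.45 ± 0.279, 0.477), Muc2 (1.24 ± 0.451, 0.245), Chga (-0.67 ± 0.274, 0.294) and Ccn2 (0.16 ± 0.267, 0.803) did not pass. The stem cell list had 1 of 19 members lower (5 when adjusted over the list alone; camera adjusted p = 0.0648; 0.0410 without non-degradable PEG replicate 1 and 0.0163 without degradable PEG replicate 2, range 0.0163 to 0.601). Wnt targets had 1 of 17 lower, also when adjusted over the list alone (0.0514; 0.0391 and 0.0240 without Matrigel replicates 1 and 3, 0.0114 without non-degradable PEG replicate 3 and 0.00288 without degradable PEG replicate 2, range 0.00288 to 0.753). Enteroendocrine genes had 1 of 14 higher, Nts, although the list as a whole leaned lower (median -0.48, camera adjusted p = 0.0721; 0.0449 and 0.0408 without replicate 3 of non-degradable or degradable PEG, range 0.0113 to 0.777). Goblet cell (0.419), interferon (0.508), p53 target (0.277) and matrix protease (0.419) lists passed only without non-degradable PEG replicate 3 (0.0321, 0.0321, 0.0105 and 0.0443; highest values over their alternatives 0.922, 0.927, 0.922 and 0.947). The lists for tuft cells (0.962), YAP/TAZ targets (0.509), fetal-like epithelium (0.913), integrins (0.819), basement membrane (0.277), epithelial defence (0.740), unfolded protein stress (0.913) and the Notch pathway (0.507) did not pass. Neither did those for BMP targets (0.823), keratins and junctions (0.998), gastric and squamous epithelium (0.913), mesenchymal cells (0.823), smooth muscle, glia and neurons (0.863), endothelium (0.457), blood cells (0.891), EHS tumour matrix (0.507), mitochondrially encoded genes (0.237) and histones (0.819). Median, mean and test differed in sign for the fetal-like (-0.02, 0.17, lower), tuft (0.08, -0.07, lower), unfolded protein (0.00, -0.04, lower), keratin (0.03, -0.05, higher), gastric (-0.12, 0.09, higher) and blood cell (-0.09, -0.11, higher) lists. Of the 35 lists, 4 passed as higher and 6 as lower with the preset correlation, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 0 with fry (8 at an unadjusted p under 0.05). Another split of the same 6 libraries passed 14. A glmTreat test against a 1.5-fold change left 0 genes (300 at an unadjusted p under 0.05). Tested against no change, where edgeR gave 190 genes, limma-voom gave 193 and DESeq2 511.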

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

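The tests of heat shock, of replicate numbers and of the other splits were chosen before the results were seen, and all other tests below were chosen after. Among the panel genes and gene lists, 12 differed in the direct comparison of the PEG gels. Axin2 had a log2 fold change of -0.51 (non-degradable against degradable) and Alpi of 2.24. The median log2 fold change was 0.90 for enterocyte genes, 0.39 for hypoxia and glycolysis, 0.35 for oxidative stress and xenobiotic and 0.27 for cholesterol synthesis genes. It was -0.76 for NF-kB and inflammation, -0.43 for immediate early, -0.25 for Paneth cell, -0.22 for DNA replication, -0.20 for actin and SRF target and -0.15 for mitosis genes. All 10 lists were lost with an estimated correlation, with adjusted p from 0.408 to 0.753.

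For the rise of immediate early genes in both PEG gels, the heat shock test was chosen before the result was seen and the others after. A broad rise of the heat-shock chaperones, as dissociation can bring, was not seen, which argues against such a broad response as the cause. The higher of the medians of 16 chaperones was -0.0463, with upper quartiles of 0.226 in non-degradable and 0.146 in degradable PEG. In the edgeR test 0 of 16 passed as higher in either gel, and 3 passed as lower in non-degradable PEG and 0 in degradable PEG. Members went both ways, and the largest rise was that of Hspa1a, 0.97 and 1.05 (adjusted p = 0.0862 and 0.0829). Hspa1b changed by 0.58 and 0.66 (adjusted p = 0.0888 and 0.0697). A rise of single chaperones therefore stays open, and so does an effect of dissociation without a broad chaperone response. No single library accounts for the rise, since the list mean was 5.36 or higher in every PEG library and 3.70 or lower in every Matrigel library. The highest camera adjusted p without any 1 library was 7.67e-15 with the preset correlation (with an estimated correlation the list was lost, adjusted p = 0.309 and 0.232). Camera with the preset correlation also passed 21 lists in another split of 6 libraries, so that p alone would not exclude a single library. In degradable PEG the list means ran from 6.67 to 7.01 with an SD of 0.189, against 3.22 to 3.70 with an SD of 0.244 in Matrigel. That gap argues against handling that differed at random from library to library as the cause in degradable PEG. An SD from 3 libraries is imprecise, so a smaller part of such handling is not excluded. In non-degradable PEG all libraries also lay above Matrigel (5.36 to 6.80), but with an SD of 0.734 a part of the size of the rise cannot be told apart from such handling. Handling that differed by matrix is confounded with the groups and was not tested.

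For the fall of Paneth cell genes in both PEG gels, all tests were chosen after the result was seen. The summed CPM of all Defa genes, 16 of 39 with counts, fell in both gels, and the smaller of the log2 differences was -3.32. Uniquely aligned reads moving between these copies can therefore be excluded as the cause. Reads with more than 1 alignment were not counted, so reads lost to indistinguishable copies were not tested. A single library can be excluded as well for the defensins, whose summed CPM was 22.1 to 44.3 in the PEG libraries and 216 to 462 in the Matrigel libraries. For the Paneth list the highest camera adjusted p without any 1 library was 1.76e-06 with the preset correlation (with an estimated correlation the list was lost, adjusted p = 0.309 and 0.232). As for the immediate early list, that p alone would not exclude a single library. An equal loss of every differentiated cell type can be excluded as the whole cause in non-degradable PEG, by a test on quartiles that replaced one on medians. The lower quartile of the enterocyte log2 fold changes, -0.0101, lay above the upper quartile of the Paneth list, -0.890. In degradable PEG the highest lower quartile among the enterocyte, goblet, enteroendocrine and tuft lists was -1.10, below the Paneth upper quartile of -0.894, while the Paneth median of -3.03 lay outside the quartiles of all 4 lists. An equal loss there cannot be told apart from a loss of Paneth cells beyond that of other types, since the members of the lists spread too widely.

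For the higher enterocyte genes in non-degradable than in degradable PEG, the test of replicate numbers was chosen before the result was seen and the others after. A single library can be excluded, since the lowest list median without any 1 library was 0.788. The smallest mean log2 difference between same-numbered libraries was 1.12. Each gel holds every replicate number, so an effect of the number alone could not produce a difference between the gels. The test of replicate numbers therefore could not have found such a cause. The scaling of the libraries can be excluded, since the lowest median under other scalings was 0.874. Against Matrigel the list was lower in degradable PEG (median -0.75, 7 lower and 0 higher of 20, call lost in 1 of 18 alternatives). In non-degradable PEG it was higher (median 0.44, 5 higher and 3 lower of 20, call lost in 12 of 18). Fewer absorptive cells in degradable PEG, or more in non-degradable PEG, may be candidate explanations that were not tested. In the direct comparison the list was lost under an estimated correlation (camera adjusted p = 0.408).

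The splits were chosen before the results were seen. The 10 splits of 6 libraries are too few for a share under 0.05. For non-degradable PEG against Matrigel, 1 of 10 splits, the real one, gave as many as 2504 genes, and the highest other gave 0 (638 at an unadjusted p under 0.05), also among the splits that part all 3 pairs of equal numbers. As many as 21 lists were passed by 2 of 10 splits, the highest other passing 21 and parting all 3 pairs. For degradable PEG against Matrigel, 1 of 10 gave as many as 1815 genes (highest other 0, with 1533 at an unadjusted p under 0.05) and 1 of 10 as many as 20 lists (highest other 18). For the gels against each other, 1 of 10 gave as many as 190 genes (highest other 23) and 3 of 10 as many as 10 lists (highest other 14). Across all 3 matrices, 100 of the 280 possible splits were run, 98 of them drawn at random. The real split alone, 1 of 100, gave as many as 2424 genes, the highest other giving 1725. A random grouping of these libraries therefore rarely gave such a count, although some other groupings also gave many genes.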

How the results depend on the processing

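Depth and 3 libraries per matrix limit these comparisons to genes with enough counts, and 74 of 100 simulated 2-fold changes were recovered. Some alternatives gave no value because genes or lists fell out under the filter of 10 CPM. Among counts and shares, 117 alternatives kept the result, 34 lowered it, 8 raised it and 4 moved it. A kept result was not an unchanged one, since a shift within a set margin was allowed. For non-degradable PEG against Matrigel, 3367 genes in a fit of the compared groups only counted as kept beside 2504. For the gels against each other, 127 genes without Matrigel replicate 3 counted as kept beside 190. For named genes that had passed, 1509 alternatives kept the call and 92 lost it, and for those that had not passed 431 made no call, 54 made 1 and 5 turned the sign. For lists that had passed, 798 kept the call and 113 lost it, and for other lists 897 made no call and 55 made 1. The cause of these differences was not tested.

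Without a filter on low counts the direct comparison of the PEG gels gave 521 genes, and DESeq2 gave 511. With a filter of 10 CPM the counts were 1569 for non-degradable PEG against Matrigel, 1011 for degradable PEG against Matrigel, 110 for the gels against each other, 660 for the overlap and 1435 for all 3 matrices, from fewer genes tested. With the replicate block they were 3877, 2783, 542, 1917 and 3894. A test against a 1.5-fold change gave 478, 437, 0 and 280 for the first 4 of these. An adjusted p under 0.01 gave 1024, 795, 6, 492 for the overlap and 1057 for all 3 matrices. Camera with an estimated correlation passed 0, 0 and 0 lists, and fry passed 0 lists for the gels against each other. The first principal component of the 500 most variable genes held 72.3% of the variance.

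With 1 library left out, the counts ran from 1189 to 3247 for non-degradable PEG against Matrigel, from 1086 to 2395 for degradable PEG against Matrigel and from 19 to 242 for the gels against each other. The overlap ran from 697 to 1410, and the count over all 3 matrices from 1507 to 3109. Lists for the gels against each other ran from 9 to 16. The log2 fold change of Lgr5 in non-degradable PEG against Matrigel ran from -0.054 to 0.14, and that of Mki67 between the gels from -0.20 to 0.051. The share of the first principal component ran from 46.8% to 57.0%, alternatives that were chosen after the data were seen.

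For degradable PEG against Matrigel, residuals of same-numbered libraries correlated with r from 0.0712 to 0.258 and others from -0.238 to 0.0392, and every library correlated best with its own number. With the replicate block Lgr5 (0.00949) and Olfm4 (0.00127) passed and the tuft list did not (0.120). Between the PEG gels the ranges were 0.0197 to 0.511 and -0.454 to 0.257, and not every library correlated best with its own number, since non-degradable PEG replicate 2 did so with degradable PEG replicate 1 (0.257). With the block Lgr5 (0.0230), Olfm4 (0.0367), Muc2 (0.0262), Cxcl1 (0.00311), Mcm3 (0.0331), Cdc45 (0.0258), Klf6 (0.0244), Ier3 (0.0122), Kdm3a (0.0167), Ndrg1 (0.0165) and Sc5d (0.0481) and the enteroendocrine (0.0113) and mitochondrially encoded (0.0340) lists passed. The block changed no other call of a named gene or list in any comparison beyond those given with non-degradable PEG against Matrigel.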
